A study of Mus musculus with 94 samples.

How the data were processed

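Total RNA of brain, liver, spleen and thymus from homozygous mutant and wild-type male mice of a C57BL/6N background was hybridised to Illumina arrays, per the labels. RNA was extracted with Trizol, cleaned with an RNeasy kit and turned into biotin-labelled cRNA with a MessageAmp kit, per the labels' protocols. GenomeStudio 2011.1 is named in the submitters' processing notes. The deposited value table holds linear intensity values that the authors had background-subtracted and normalized, as the values show: 19.1 to 29.1 percent of an array's values lay below 0, and arrays shared their quantiles within a line and tissue but not between them, as near-equal medians and upper quartiles show. The sets were therefore taken as normalized separately, and tests compare arrays only within a set, except where tissues were quantile-normalized together. The normalization method is not given in the sources used here. A second table of raw signals carries column names that match no sample label, so its 188 columns of per-sample values were not used. The planned start from raw signals was replaced by the value table for that reason.

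Groups came from the labels. Wild types were assigned to a line by the mouse numbers in the labels, with 1 mouse placed by elimination. Separate mice gave the replicates of a group. Before the data were examined, the groups, tests, alternatives, gene lists and the rule for named genes were fixed. The noise limit and the offset of 16 below were set later, after the value table was opened and before any probe was tested, in place of detection p-values and of the planned floor of 1. The floor of 1 was run as an alternative and gave far fewer probes in spleen. Probes were named from the platform table, which gave 23978 probes 1 gene symbol, 0 several and 1719 none. Of its Entrez identifiers, 23962 probes matched a RefSeq gene table of the mouse assembly GRCm38.p6, which gave chromosomes and distances to the targeted gene.

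Values were set to at least 0, 16 was added and log2 was taken. A probe was tested in a tissue when its value exceeded 1.64 times the noise of the array (root mean square of its negative values) on 3 or more arrays. limma 3.58.1 in R 4.3.3 fitted the 6 groups of a tissue in 1 model with a shared spread, and labelled mutants were compared with wild types of their line. Tests were two-sided with Benjamini-Hochberg adjustment at a threshold of 0.05. A group not above noise on all its arrays has only a bound, given as at least N-fold: the mean log2 intensity of the brighter group minus that of the dim group with each value raised to at least the noise limit. Tissue differences used an F test over the tissue contrasts of a line with the mouse as a random block. Line differences used an F test within a tissue. The 44 gene lists, with 786 genes matched and 4 unmatched, were tested where 5 or more genes were tested, 1 probe per gene (the highest mean signal), with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry. Camera called 58 of 318 list tests, the estimated correlation 1 and fry 10. Lists called in no comparison by camera were those of B cells, plasma cells, immature thymocytes, astrocytes, neurons, oligodendrocytes, striatum, cerebellum, choroid plexus, hypothalamic hormones, HMG-box and linker histone genes, ribosomal proteins, the circadian clock, substrain differences, PPAR-alpha targets, lipogenesis, glucose and xenobiotic metabolism and male-biased and female-biased liver genes. Among these the smallest camera adjusted p was 0.0556, for cerebellar genes. Of single substrain genes 0 passed by limma.

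Named genes were, per line and tissue, the 5 largest rises and 5 largest falls among probes that passed, 1 probe per gene, and the targeted gene. Where under 4 genes passed, the 3 rises and 3 falls of smallest p were added. Genes that passed in 2 or more tissues or lines, the 5 strongest tissue differences of a line, and up to 4 members of a list called by camera completed the rule. A further probe of a named gene was taken to move with it when it had the same direction at an unadjusted p under 0.05.

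The scripts were tested on simulated data. For brain of the Hmgn1 line, with 200 of 19196 probes changed, 45 percent of those changed by 0.5 and 86 percent of those changed by 1 on the log2 scale were recovered, and 11 of 142 calls were false. For spleen of the Hmgn1 line, with 18519 probes, the shares were 54 percent and 98 percent, and 7 of 159 calls were false.

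Alternatives were log2 with a floor of 1, no filter or a stricter filter (2.33 times the noise on 50 percent of the arrays) on dim probes, array weights, only the arrays of a line and tissue, the replicate number as a block, leaving out each array or mouse, no mouse block, and tissues normalized apart. After the data were seen, quantile normalization of the 3 lines of a tissue together, the replicate number as a linear covariate (wild types 1 to 4, labelled mutants 5 to 8), a skeletal muscle score as a covariate in thymus, the whole chromosome of the target and further tests of the probes near Hmgn1 were added. Figures were drawn with matplotlib 3.10.9.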

Results

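Gene expression was measured in brain, liver, spleen and thymus of male mice, 17 weeks old, from 3 lines that carry a mutation in Hmgn1, Hmgn3 or Hmgn5. These genes encode high mobility group N proteins, small chromatin proteins that bind nucleosomes. The series asked how homozygous mutants differed from wild types. Each line and tissue had 4 mutant and 4 wild-type arrays, except 3 wild-type liver arrays in the Hmgn1 and Hmgn5 lines, which made 94 arrays from 24 mice. The number of arrays limited the precision. Between 12238 and 16422 of 25697 probes lay above the noise of an array. Values are deposited normalized intensities, given as mean ± SD, and log2 changes are labelled mutant minus wild type on the log2(intensity + 16) scale with a standard error (SE). That scale understates the change of dim probes. Adjusted p-values are from limma with Benjamini-Hochberg adjustment unless another test is named.

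In the Hmgn3 line both Hmgn3 probes fell in brain, spleen and thymus of the labelled mutants. The changes of the first probe were -0.55 (SE 0.0862, adjusted p = 0.0175) in brain, -1.70 (SE 0.12, adjusted p = 3.43e-09) in spleen and -1.46 (SE 0.129, adjusted p = 5.36e-07) in thymus. In spleen its intensity was 395 ± 53.6 in wild types and 111 ± 15.7 in labelled mutants (n = 4 each). In brain 2051 ± 285 remained of 2997 ± 111 (n = 4 each). Liver was near the noise, at 17.1 ± 5.44 against 7.62 ± 5.86 (n = 4 each), and did not pass (adjusted p = 0.871). The second probe was at 14.2 ± 5.80 against 4.39 ± 4.54 there (adjusted p = 0.718). The unadjusted limma p-values of the 2 probes in liver were 0.0083 and 0.00269.

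The Hmgn1 probe did not pass in any tissue of the Hmgn1 line. Its change was -0.23 (SE 0.071, adjusted p = 0.824) in brain, 0.10 (adjusted p = 0.86) in liver, -0.11 (adjusted p = 0.739) in spleen and -0.41 (SE 0.12, adjusted p = 0.284) in thymus. In brain the probe read 2647 ± 93 in wild types and 2259 ± 70.4 in labelled mutants (n = 4 each). Its unadjusted limma p-values were 0.00408 in brain, 0.286 in liver, 0.456 in spleen and 0.0021 in thymus. In brain and thymus every labelled mutant array lay below every wild-type array. The Hmgn5 probe fell in thymus of the Hmgn5 line, from 352 ± 65.2 to 157 ± 18.1 (n = 4 each, log2 change -1.08, adjusted p = 0.00399). It rose in liver, from 789 ± 76.1 (n = 3) to 1196 ± 69.2 (n = 4, log2 change 0.59, adjusted p = 0.00181). It did not pass in brain (0.39, adjusted p = 0.64) or spleen (-0.39, adjusted p = 0.23). The sources used here do not place the probes relative to the mutated part of each gene, so these probes check the labels only where they fell. Mice are therefore called labelled mutants throughout, and directions rest on the labels. Hmgn2 passed in none of the 12 comparisons, with a smallest adjusted p of 0.126 among the HMGN genes not targeted in a line.

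**Figure D1:**
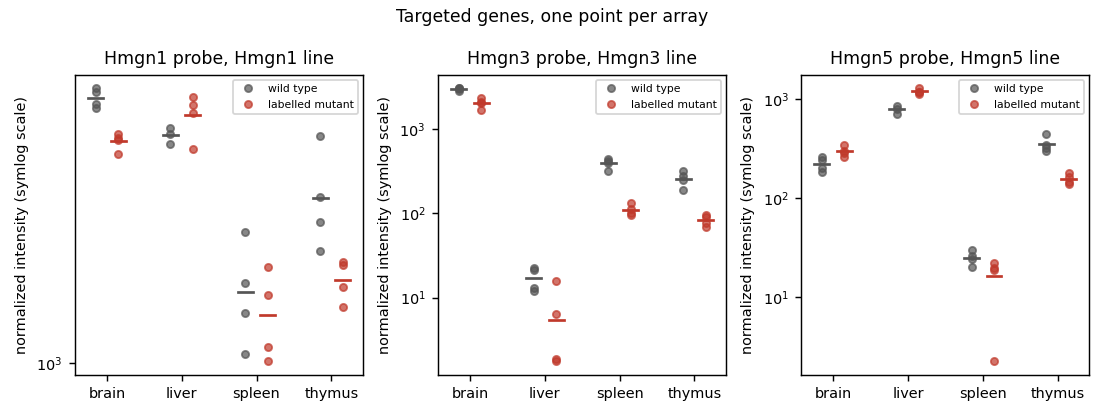
Normalized intensity (symlog scale, linear below 10) of 1 probe of each targeted gene in its own line, by tissue. Points are arrays and bars are means. In thymus the Hmgn3 arrays and the Hmgn5 arrays of labelled mutants lay below those of wild types, while Hmgn5 in liver was higher, at 1196 against 789.

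**Figure D2:**
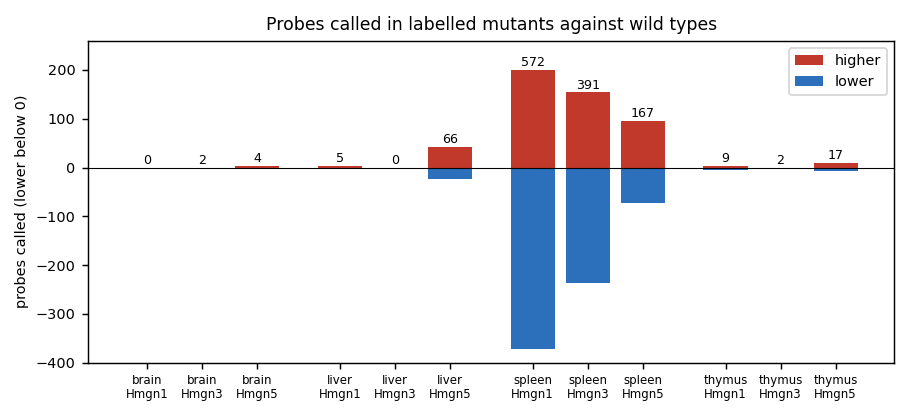
Probes with an adjusted p under 0.05 in each line and tissue, with higher probes above and lower probes below 0 and the total printed on each bar. Spleen held 572, 391 and 167 of them in the Hmgn1, Hmgn3 and Hmgn5 lines.

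In liver of the labelled Hmgn1 mutants, Mrap, which encodes an accessory protein of the melanocortin receptor of the adrenal gland, fell from 687 ± 25.1 (n = 3) to 158 ± 23.3 (n = 4). Its log2 change was -2.03 (SE 0.125, adjusted p = 5.97e-09). Pigp, a gene of glycosylphosphatidylinositol anchor synthesis, fell from 806 ± 75.9 to 467 ± 63.2 (-0.77, adjusted p = 0.00363). Cryzl1 rose from 325 ± 35.4 to 498 ± 19.4 (0.60, adjusted p = 0.00429). Pdlim2 (at least 1.18-fold, adjusted p = 0.0271) and 4930404N11Rik (at least 1.00-fold, adjusted p = 0.0207) rose from wild-type levels not above noise. These 5 of 15732 probes were all that passed. The further probe of Pdlim2 did not move with the first (-0.36). Only Mrap passed with the arrays of this line alone or with the replicate number as a covariate, 3 probes passed with a floor of 1 or with the lines quantile-normalized together, and 17 with no filter on dim probes. With the covariate the median size of the change of the 5 probes was 0.69 (SE 0.172), against 0.67 (SE 0.108) without it, so the error grew and the change did not shrink. Macrophage genes lay lower as a list (median -0.32, 10 of 12 genes lower, camera adjusted p = 0.00158, adjusted p = 0.424 with an estimated correlation). Their members included Lyz2 at -0.75 and C1qc at -0.65, and 0 of them passed over all probes or adjusted over the list alone. Genes linked to HMGN proteins elsewhere were lower (median -0.28, camera adjusted p = 0.0113, adjusted p = 0.118 with an estimated correlation). Within that list Olig1, which lies within 10 Mb of Hmgn1, was at -1.38 and Sox9 at -0.63. Of the members 0 passed over all probes and 3 were lower when adjusted over the list alone. Fibroblast genes (adjusted p = 0.438 with an estimated correlation), cholesterol synthesis genes (adjusted p = 0.677), endothelial genes (adjusted p = 0.192) and p53 targets (adjusted p = 0.327) were also lower by camera. Glucocorticoid-induced genes were higher (median 0.20, camera adjusted p = 0.0397, adjusted p = 0.438 with an estimated correlation). Each of these 7 lists lost its call with the covariate.

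In thymus of the labelled Hmgn1 mutants, Cbr3, a carbonyl reductase, rose from 56.7 ± 3.49 to 231 ± 35.1 (n = 4 each, 1.75, SE 0.124, adjusted p = 1.14e-08). Olig1, a transcription factor of the oligodendrocyte lineage, rose from 5.08 ± 2.27 to 29.4 ± 7.17 (1.10, adjusted p = 0.00211). Mrap fell from 128 ± 39.8 to 25.2 ± 6.71 (-1.77, adjusted p = 0.00256). The chemokine Ccl5 fell from 117 ± 41.8 to 39.4 ± 10.3 (-1.23, adjusted p = 0.0117). Ttc3 (-1.14, adjusted p = 0.0006), Elmo1 (-0.55, adjusted p = 0.023) and Prr5l fell too, Prr5l to a level not above noise (at least 3.28-fold lower, adjusted p = 0.00191). None of 7 further probes of Ttc3 and 13 of Elmo1 moved with the named one. In all, 9 of 18202 probes passed, while 48 passed with array weights, 3 (Cbr3, Olig1 and Mrap) with the arrays of this line alone and 1 (Cbr3) with the replicate number as a covariate, where the median size of the change of the 9 probes was 0.88 (SE 0.201), against 1.10 (SE 0.143) without it. Interferon-stimulated genes were lower as a list (median -0.18, 13 of 15 lower, camera adjusted p = 0.00292, adjusted p = 0.272 with an estimated correlation), with Ifit2 at -0.47 and Irf7 at -0.50. Of these genes 0 passed over all probes and 1 when adjusted over the list alone. Lower by camera were also antigen presentation genes (median -0.16), natural killer cell genes (-0.09), T cell genes (-0.10, Il7r at -0.62) and thymic stroma genes (-0.14, Ccl21a at -1.65). Their adjusted p-values with an estimated correlation were 0.272, 0.272, 0.445 and 0.313. Higher by camera were glucocorticoid-induced genes (median 0.26), smooth muscle genes (0.45), neutrophil genes (0.29), heat shock chaperones (0.23), proliferation genes (0.11), glutathione genes (0.11) and fibroblast genes (0.20). None of these kept an adjusted p under 0.272 with an estimated correlation. With the covariate, interferon-stimulated genes (0.0356), antigen presentation genes (0.0391) and, by the direction of camera, T cell genes (-0.00347) turned direction. Neutrophil genes alone of the 12 lists kept their call with it. With the muscle score of each array as a covariate instead, glutathione genes, fibroblast genes and T cell genes lost their call (adjusted p = 0.132, 0.132 and 0.0572) and the other 9 lists kept it. The medians of these 3 were then 0.06, 0.20 and -0.09, and all 3 kept their call without labelled mutant 4. Proliferation genes alone of the 12 lists lost theirs without that array (camera adjusted p = 0.0778). The skeletal muscle genes scored 8.08 in the Hmgn1 thymus of labelled mutant 4 and 5.40 in that of labelled mutant 2.

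In brain of the Hmgn1 line 0 of 19196 probes passed by limma, and 743 had an unadjusted p under 0.05. The genes of smallest p that did not pass included Sgk1, a glucocorticoid-regulated kinase, at 2536 ± 440 against 4648 ± 285 (n = 4 each, 0.88, adjusted p = 0.0615). Vmn1r214 (0.56) and Clec4a2 (at least 1.14-fold, from a level not above noise) were also higher. Kcnj6, a potassium channel gene, was at -1.28 and Mrps27 at -0.99, and Ctso was lower at a level not above noise. Glucocorticoid-induced genes were higher as a list (median 0.15, 11 of 13 higher, camera adjusted p = 2.19e-06, adjusted p = 0.216 with an estimated correlation), with Per1 at 0.47 and Nfkbia at 0.44. Immediate early genes were higher (median 0.22, camera adjusted p = 0.000107, adjusted p = 0.235 with an estimated correlation), with Egr2 at 0.74 and Arc at 0.65. Of the 13 and 18 genes 0 passed over all probes, and 3 and 6 were higher when adjusted over the list alone.

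In spleen of the Hmgn1 line 572 of 18519 probes passed, 200 higher and 372 lower in labelled mutants. The chaperone Hsph1 rose from 161 ± 48.4 to 390 ± 115 (n = 4 each, 1.19, adjusted p = 0.0177). An Actb probe (1.22), Zfp52 (0.88), Arid5a (0.86) and the chemokine receptor Cxcr4 (0.86) rose. Stap1 (-1.26), the splicing factor Srsf5 (-1.22), Snx2 (-1.07), the macrophage lysozyme Lyz2 (-1.04) and Tank (-1.03) fell. Mrap (-0.75), Ttc3 (-0.65) and Pigp (-0.81) fell here as well. No further probe of Stap1, Lyz2, Ttc3 or Pigp moved with the named one, and 1 of 4 further Actb probes was lower (-0.84). Heat shock chaperones were higher, 13 of 13 (median 0.26, camera adjusted p = 0.00103, adjusted p = 0.275 with an estimated correlation), with 1 passing over all probes and 5 when adjusted over the list alone. Glucocorticoid-induced genes were higher (median 0.32, camera adjusted p = 0.00487, adjusted p = 0.249 with an estimated correlation), with Per1 (0.74), Errfi1 (0.63) and Pdk4 (0.62) passing over all probes and 6 higher when adjusted over the list alone. Smooth muscle genes were higher (0.31, adjusted p = 0.539 with an estimated correlation). With values floored at 1 before log2, the treatment planned for this table, 25 probes passed, and 3 passed with only the arrays of this line in the model. Leaving out 1 array gave 9 to 1551. With the replicate number of the labels as a linear covariate 0 passed, and the median size of the change of the 572 probes went from 0.53 (SE 0.129) to 0.25 (SE 0.166). Smooth muscle genes (-0.0612) and Lyz2 (0.0288) turned direction with it.

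In spleen of the Hmgn3 line 391 probes passed, 154 higher and 237 lower. Besides Hmgn3, Stap1 fell from 209 ± 55.3 to 71 ± 35.6 (n = 4 each, -1.43, adjusted p = 0.0168). The RNA helicase Ddx5 (-1.39), Elmo1 (-1.32), the elongation factor Eef2 (-1.31) and Snx2 (-1.23) fell. An Actb probe (1.05), the glucocorticoid-induced Tsc22d3 (0.91), the actin-bundling gene Fscn1 (0.86), the T cell coreceptor Cd4 (0.84) and Golga2 (0.82) rose. No further probe of Stap1, Tsc22d3 or Golga2 moved with the named one, and 1 of 4 further Actb probes was lower (-1.11). Smooth muscle genes were higher, 7 of 8 (median 0.38, camera adjusted p = 0.0209, adjusted p = 0.871 with an estimated correlation), with 0 passing over all probes and 4 when adjusted over the list alone. With a floor of 1, 41 probes passed, and 5 passed with only this line's arrays. Leaving out 1 array gave 8 to 717. With the replicate number as a covariate 2 passed, both of them Hmgn3 probes, and the median size of the change of the 391 probes went from 0.56 (SE 0.132) to 0.29 (SE 0.166). Smooth muscle genes turned direction with it (-0.0397).

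In thymus of the Hmgn3 line the 2 Hmgn3 probes alone passed of 18202, and 1148 had an unadjusted p under 0.05. Ncl (0.84), Hbb-bt (1.38) and Acaa1a (0.39) were higher and Gtpbp4 (-0.52), Whrn (-0.53) and Msc (-0.52) lower without passing, with adjusted p-values from 0.248 to 0.332. Skeletal muscle genes were higher in 15 of 15 (median 1.43, camera adjusted p = 3.14e-11, adjusted p = 0.333 with an estimated correlation). Acta1 was at 3.29, Tnnc2 at 3.01 and Tnni2 at 2.37, and 0 members passed over all probes or adjusted over the list alone. Of the 4 labelled mutants, 2 carried the muscle score, at 8.26 and 7.76, above the highest wild type at 5.88. Beside it, oxidative phosphorylation genes were higher (median 0.21, 22 of 23 higher, camera adjusted p = 2.02e-07, adjusted p = 0.333 with an estimated correlation), with Cox4i1 at 0.58. Fat cell genes (median 0.54), fibroblast genes (0.25), glutathione genes (0.17), immediate early genes (0.07), glucocorticoid-induced genes (0.14) and smooth muscle genes (0.31) were also higher by camera. T cell genes were lower (median -0.12, camera adjusted p = 0.0125, adjusted p = 0.333 with an estimated correlation), with Thy1 at -0.38 and 4 lower when adjusted over the list alone. Interferon-stimulated genes were lower (median -0.18, adjusted p = 0.409 with an estimated correlation). The smallest adjusted p with an estimated correlation in this thymus was 0.333. With the muscle score of each array as a covariate, each of the 9 other lists lost its call (adjusted p from 0.1001 to 0.968). The median was then -0.06 for T cell genes, -0.11 for interferon-stimulated genes, 0.09 for oxidative phosphorylation genes, 0.28 for fat cell genes, 0.15 for fibroblast genes, 0.06 for glutathione genes, 0.07 for glucocorticoid-induced genes and -0.01 for smooth muscle genes, while that of immediate early genes was larger, at 0.11. Without labelled mutant 1, the array at a score of 8.26, smooth muscle genes alone lost their call (camera adjusted p = 0.0545). Oxidative phosphorylation genes (camera adjusted p = 0.000117, median 0.15) and T cell genes (camera adjusted p = 0.0086, median -0.10) were among those that kept it. The array at 7.76 stayed in that fit. With the replicate number as a covariate, interferon-stimulated genes (0.143), T cell genes (0.0423) and smooth muscle genes (-0.167) turned direction. With array weights 11 probes passed.

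**Figure D3:**
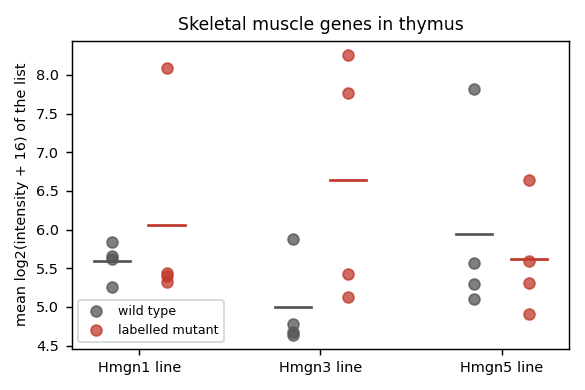
Mean log2(intensity + 16) of skeletal muscle genes in each thymus array, by line. Points are arrays and bars are means. Labelled Hmgn3 mutants at 8.26 and 7.76, 1 labelled Hmgn1 mutant at 8.08 and 1 Hmgn5-line wild type at 7.82 stood above the others.

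In liver of the Hmgn3 line 0 of 15732 probes passed by limma, 765 had an unadjusted p under 0.05, and 21 passed with a floor of 1. Endothelial genes were higher as a list, 9 of 11 (median 0.14, camera adjusted p = 0.00122). This was the 1 list of 318 list tests that held with an estimated correlation (adjusted p = 0.0324, fry adjusted p = 0.0126). Egfl7 (0.46), Esam (0.33) and Tek (0.29) had the largest changes, with 0 passing over all probes and 2 when adjusted over the list alone. Aqp1 (0.50) and Mrc1 (0.57) were higher and the haemoglobin gene Hba-a1 (-1.19), the apoptosis gene Bbc3 (-0.61) and Ube2o (-0.43) lower without passing. Erythroid genes were lower (median -0.08, adjusted p = 0.182 with an estimated correlation). Cholesterol synthesis genes (-0.28), acute phase genes (-0.11) and heat shock chaperones (-0.09) were lower by camera, acute phase genes with a turned direction without wild type 2 (0.00513). Fibroblast (0.16), smooth muscle (0.16) and macrophage genes (0.06, Adgre1 at 0.64) were higher by camera. Their adjusted p-values with an estimated correlation ran from 0.182 to 0.525.

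In brain of the Hmgn3 line the 2 Hmgn3 probes alone passed, and 2046 probes had an unadjusted p under 0.05. The genes of smallest p that did not pass were Ccdc42, Slc16a3 and Slc35c1, not above noise in wild types (at least 1.29-fold, 1.54-fold and 1.16-fold higher), S100a9 (-1.11) and Aff1 (-0.43), and Zfp13, not above noise in labelled mutants (at least 2.57-fold lower), with adjusted p-values from 0.0521 to 0.0998. Immediate early genes were higher (median 0.21, 15 of 18, camera adjusted p = 0.00265, adjusted p = 0.48 with an estimated correlation), with Junb at 0.71 and Fos at 0.56. Heat shock chaperones (median -0.12, Bag3 at -0.37) and erythroid genes (-0.22) were lower by camera, at an adjusted p of 0.48 and 0.375 with an estimated correlation. Skeletal muscle genes were higher (median 0.47, adjusted p = 0.53 with an estimated correlation). Their score was 8.04 in labelled mutant 2 and 5.78 to 6.02 in the others, and the median was -0.02 without that array. With only this line's arrays 0 probes passed and with the replicate number as a covariate 1, an Hmgn3 probe, while the median size of the change of the 2 probes went from 0.56 (SE 0.0813) to 0.67 (SE 0.114). With a floor of 1, 18 probes passed, and 66 without labelled mutant 1.

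In brain of the labelled Hmgn5 mutants, Mpp1, a membrane scaffold gene, rose from 402 ± 14.7 to 802 ± 47.9 (n = 4 each, 0.97, SE 0.0878, adjusted p = 3.69e-06). Gab3, which encodes an adaptor of growth factor signalling, rose from 119 ± 6.23 to 225 ± 20.8 (0.83, adjusted p = 0.00813). Acads (at least 1.71-fold) and Fam83f (at least 1.23-fold) rose from levels not above noise, and the further Acads probe did not move with the first (0.17). On the first Acads probe labelled mutant 3 read 21.9, while the other labelled mutants lay near the noise limit, at 6.83 to 8.76. Those 4 of 19196 probes passed, and 0 of 27 lists did. Without labelled mutant 1 the count was 72, and without wild type 2 or labelled mutant 4 it was 1. With only this line's arrays it was 2 and with the replicate number as a covariate 1 (Mpp1), where the median size of the change of the 4 probes went from 0.75 (SE 0.104) to 0.53 (SE 0.134).

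In liver of the labelled Hmgn5 mutants 66 probes passed, 43 higher and 23 lower. Mup21, a major urinary protein gene, fell from 14653 ± 1667 (n = 3) to 5642 ± 345 (n = 4, -1.37, SE 0.128, adjusted p = 1.14e-05). The melanin enzyme gene Dct fell from 494 ± 53.5 to 116 ± 55.3 (-2.04, adjusted p = 0.00308) and the water channel gene Aqp4 from 144 ± 69.3 to 22.6 ± 12.7 (-2.01, adjusted p = 0.00103). Sult5a1 (-1.46) and Spsb4 (-1.31) fell. Dnaic1 (1.54), Snhg11 (from 145 ± 10.8 to 368 ± 29.6), the transcription regulator Id1 (1.21), Tpm2 (1.15), Grhl1 (1.14) and Mpp1 (0.98) rose. Oxidative phosphorylation genes were lower, 21 of 24 (median -0.07, camera adjusted p = 0.00408, adjusted p = 0.765 with an estimated correlation), with Sdhb at -0.31. The count was 29 with a floor of 1, 15 with only this line's arrays in the model and 1, Mup21, with the replicate number as a covariate. There the median size of the change of the 66 probes stayed (0.76 without and 0.75 with the covariate) and its SE grew from 0.133 to 0.210.

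In thymus of the labelled Hmgn5 mutants 17 probes passed. Xlr4c rose from 80.7 ± 17.8 to 225 ± 49.2 (n = 4 each, 1.31, adjusted p = 0.00045) on 1 of 2 probes, the other being at -0.20. Gab3 (1.15), Mpp1 (0.87), Rhbdd3 (0.68) and Olfr262 (at least 1.20-fold) rose. The tight junction gene Cldn1 (-0.97), Vcpkmt (-0.81) and Tmx1 (-0.72) fell. Dnmt3l, a cofactor of DNA methyltransferases, and the chemokine gene Ccl12 fell to levels not above noise (at least 2.84-fold and 1.48-fold lower). Interferon-stimulated genes were lower, 14 of 15 (median -0.15, camera adjusted p = 0.0078, adjusted p = 0.606 with an estimated correlation), with Irf7 at -0.61. Endothelial (0.23) and fat cell genes (0.28) were higher by camera, both at an adjusted p of 0.606 with an estimated correlation. Wild type 1 stood apart in skeletal muscle genes of the thymus, at a score of 7.82 in the Hmgn5 line. Without that array the medians were 0.34 and 0.40, and with the muscle score as a covariate 0.28 and 0.33, and both lists kept their call each time. Both lost it without wild type 3, wild type 4 or labelled mutant 4. With only this line's arrays 0 probes passed by limma, against 1664 at an unadjusted p under 0.05 in the shared model, and 1 (Mpp1) passed with the replicate number as a covariate. There interferon-stimulated genes turned direction (0.0768), while the median size of the change of the 17 probes went from 0.72 (SE 0.126) to 0.79 (SE 0.178).

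In spleen of the labelled Hmgn5 mutants 167 probes passed, 95 higher and 72 lower. Gab3 rose from 73.6 ± 11.5 to 157 ± 27.5 (n = 4 each, 0.94, adjusted p = 0.000221). An Actb probe (1.72), the mesothelial gene Upk3b (1.24), Igfbp6 (1.22), Retnla (0.96) and Xlr4c (0.89, its other probe at 0.09) rose. The B cell chemokine gene Cxcl13 (-1.08), Ppp1cb (-0.95), Mak16 (-0.85), Lypla1 (-0.84) and Fcrl1 (-0.81) fell. No further probe of Mak16, Lypla1 or Fcrl1 moved with the named one, and 1 of 4 further Actb probes was lower (-0.98). Fibroblast genes were higher, 12 of 13 (median 0.43, camera adjusted p = 1.05e-05, adjusted p = 0.298 with an estimated correlation), with Dcn at 0.68. Of the probes used for the list, 1 per gene, 0 passed over all probes and 9 when adjusted over the list alone. A probe of Fbln1, a member of the list, did pass over all probes in this spleen. T cell genes were higher (median 0.24, camera adjusted p = 0.000954, adjusted p = 0.308 with an estimated correlation), where Cd3d (0.72) and Cd27 (0.59) passed over all probes and 5 when adjusted over the list alone. Fat cell (0.39) and smooth muscle genes (0.31) were higher by camera, at an adjusted p of 0.298 and 0.308 with an estimated correlation. Proliferation (-0.17), erythroid (-0.38) and pancreatic acinar genes (-1.31) were lower, at an adjusted p of 0.479, 0.561 and 0.649 with an estimated correlation. The acinar score varied from array to array, from 4.22 to 10.6 in this line's labelled mutants. With the replicate number as a covariate 0 probes passed and the median size of the change of the 167 probes went from 0.59 (SE 0.124) to 0.30 (SE 0.161). Smooth muscle genes turned direction with it (-0.0515). By the other alternatives 56 passed with only this line's arrays and 48 with a floor of 1. Leaving out 1 array gave 8 to 416.

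The spleen changes of the 3 lines resembled each other, although each line had its own wild types. Across genes, which are not independent, log2 changes correlated at r = 0.595 (Hmgn1 and Hmgn3), 0.513 (Hmgn1 and Hmgn5) and 0.513 (Hmgn3 and Hmgn5). The Hmgn1 and Hmgn3 lines shared 89 lower probes against 4.76 for independent lists. In spleen 158 genes passed in 2 or more lines, 27 of them in 3 lines, and 152 moved in 1 direction. Stap1, Ddx5, Elmo1, Srsf5, Lyz2, Snx2, Slc44a2, Cxcl13 and Ivns1abp were among those that fell. Cxcl13 changed by -0.97, -0.90 and -1.08 in the 3 lines, and with the replicate number as a covariate it turned direction in the Hmgn1 (0.0583) and Hmgn3 line (0.130), as did Lyz2 in the Hmgn3 line (0.0410). No gene passed in 2 lines in another tissue. Arrays were scored on the change seen in the other lines. In the Hmgn1 line the wild types numbered 1 to 4 scored (projections of centred log2 values) -16.2, -10.5, -9.37 and -1.76 and the labelled mutants -1.39, 12.3, 11.3 and 15.6.

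**Figure D4:**
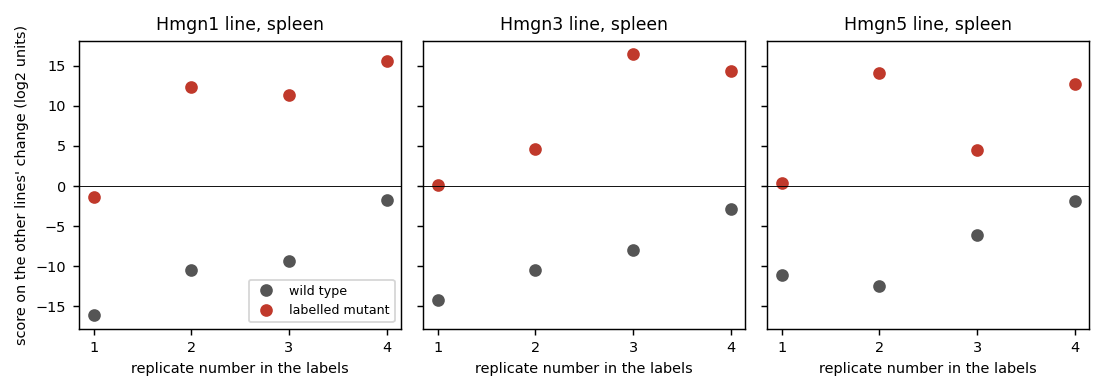
Score of each spleen array on the mean change of the other lines (log2 units), against the replicate number in the labels. Points are arrays, wild types in grey and labelled mutants in red. The correlation of score and number within the 6 groups averaged 0.80.

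Differences between tissues were tested within each line with the mouse as a block. The labelled mutant effect differed between tissues for 98 probes in the Hmgn1 line, 38 in the Hmgn3 line and 47 in the Hmgn5 line. In the Hmgn1 line Cbr3 (adjusted p = 4.69e-08) and Olig1 (adjusted p = 4.52e-07) led, followed by Pyy, Zdhhc17 and Mrap. In the Hmgn3 line Gpr174, Fabp3, Snx2, Fcrl1 and Hmgn3 led. In the Hmgn5 line Gpr153, Spsb4, Mup21, Dnmt3l and Uchl5 led. Of these, Zdhhc17 in the Hmgn1 line, Gpr174, Snx2 and Fcrl1 in the Hmgn3 line and Gpr153 and Uchl5 in the Hmgn5 line had their largest change in spleen, where nearly all calls were lost with the replicate number as a covariate. That covariate was not run for differences between tissues or for average changes. On average over tissues 412, 63 and 35 probes changed. An average can rest mostly on spleen. Srsf5 in the Hmgn1 line averaged -0.50, with -0.16, -0.15, -1.25 and -0.44 in brain, liver, spleen and thymus. Others did not rest on it, such as Mpp1 in the Hmgn5 line, at 1.00, 0.86, 0.61 and 0.92. How many averages rest on spleen was not counted. Leaving out 1 mouse gave 10 to 640, 0 to 85 and 17 to 95 probes for tissue differences and 29 to 976, 2 to 133 and 6 to 98 for average changes. Mrap passed in 3 tissues of the Hmgn1 line, and Mpp1 and Gab3 each in 3 tissues of the Hmgn5 line. Between lines, effects differed for 1 probe in brain (Mpp1, adjusted p = 0.000125), 27 in liver (led by Mrap and Mup21), 3 in spleen (Hmgn3 and Gab3) and 9 in thymus (led by Cbr3, Hmgn3 and Xlr4c). The lines were normalized apart, and liver gave 10 probes with the lines quantile-normalized together. The offset of 16 understates changes more where a probe is dimmer, so it enters differences between tissues and between lines. By means, the second Hmgn3 probe was 3.24-fold lower in liver and 3.81-fold lower in spleen of the labelled Hmgn3 mutants. Its log2 changes in the tissue models were -0.57 and -1.78.

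Genes near the targeted gene were compared with other chromosomes. Over the 4 tissues of the Hmgn1 line 12 of 119 tested probes within 10 Mb of Hmgn1 passed, against 536 of 19954 on other chromosomes (two-sided Fisher exact p = 0.000102), and in spleen alone 8 of 98 against 530 of 16796 (Fisher exact p = 0.0129). Spleen was left out of a further comparison, not planned, after its many changes were seen. In brain, liver and thymus 7 of 118 passed against 6 of 19323 (Fisher exact p = 4.22e-13), and the genes were Cbr3, Cryzl1, Mrap, Olig1, Pigp and Ttc3. Over the 4 tissues 1 of 103 other probes near Hmgn3 passed in the Hmgn3 line against 347 of 19468, and 1 of 95 near Hmgn5 in the Hmgn5 line against 228 of 19890 (Fisher exact p = 1 for each). On the whole X chromosome, a comparison chosen after the data were seen, 13 of 702 probes passed in the Hmgn5 line against 228 of 19890 elsewhere (Fisher exact p = 0.104). In spleen alone it was 7 of 579 against 157 of 16755 (Fisher exact p = 0.507), and in brain, liver and thymus 9 of 678 against 71 of 19261 (Fisher exact p = 0.00155), with Mpp1, Gab3 and Xlr4c among the 9.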

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

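The tests that weigh an explanation of a pattern below were chosen after the result was seen, except the comparison of genes near Hmgn1 over the 4 tissues, which was planned, as were the counts of other splits of the samples.

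A sample far from the others of its group was found in 11 of 266 groups of 4 tested (158 for genes and 108 for lists), and chance alone flags about 1 in 20. The gap of the far array, as a share of the group's range, was 0.865 for Arid5a in spleen of labelled Hmgn1 mutants, 0.84 for Acads in brain of labelled Hmgn5 mutants and 0.967 for Grhl1 and 0.863 for Mup21 in liver of labelled Hmgn5 mutants. It was 0.978 for Tmx1 in thymus of labelled Hmgn5 mutants, 0.954 for Ccl12 in thymus of Hmgn5-line wild types, 0.85 for Hmgn3 in liver of Hmgn3-line wild types and 0.856 for Hmgn5 in spleen of labelled Hmgn5 mutants. For lists it was 0.896 for skeletal muscle genes in brain of labelled Hmgn3 mutants, 0.839 for antigen presentation genes in thymus of Hmgn1-line wild types and 0.887 for skeletal muscle genes in thymus of Hmgn3-line wild types.

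Effects that differed between tissues were found for 98, 38 and 47 probes in the Hmgn1, Hmgn3 and Hmgn5 lines. In the Hmgn1 line the adjusted p was 4.69e-08 for Cbr3, 4.52e-07 for Olig1, 0.000638 for Pyy, 0.0024 for Zdhhc17 and 0.0024 for Mrap. In the Hmgn3 line it was 0.00994 for Gpr174, 0.0125 for Fabp3, 0.0125 for Snx2, 0.0149 for Fcrl1 and 0.0225 for Hmgn3. In the Hmgn5 line it was 0.000288 for Gpr153, 0.000317 for Spsb4, 0.000317 for Mup21, 0.000423 for Dnmt3l and 0.000629 for Uchl5. Effects that differed between lines were found for 1 probe in brain, 27 in liver, 3 in spleen and 9 in thymus. The adjusted p was 0.000125 for Mpp1 in brain. In liver it was 5.7e-06 for Mrap, 7.52e-05 for Mup21 and 0.000738 for Mpp1. In spleen it was 2.03e-07 for Hmgn3 and 0.0057 for Gab3. In thymus it was 4.03e-07 for Cbr3, 2.45e-06 for Hmgn3 and 0.00147 for Xlr4c.

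Of 35 splits of the arrays or mice of a line, only 1, the real one, gave as many probes in spleen of the Hmgn1 line (572, highest other 147), the Hmgn3 line (391, highest other 94) and the Hmgn5 line (167, highest other 11). The real split is always counted, so 1 in 35 is the smallest share these counts can give. The shares were not adjusted over the comparisons, so they make chance less likely and do not exclude it. The real split was also alone for thymus of the Hmgn1 line (9, highest other 1) and Hmgn3 line (2, highest other 0). It was alone for liver (66, highest other 11) and, by a narrow margin, brain (4, highest other 3) of the Hmgn5 line. The same holds for tissue differences in the Hmgn1 line (98, highest other 44) and for average changes in the Hmgn1 (412, highest other 40), Hmgn3 (63, highest other 18) and Hmgn5 line (35, highest other 19). In liver of the Hmgn1 line other splits gave as many (5, highest other 17, 3 splits as large, the real one included). In brain of the Hmgn1 line (0, highest other 5) and liver of the Hmgn3 line (0, highest other 3) 0 probes had passed, so each of the 35 splits gave as many whatever the arrays held, and the splits decide nothing. Other splits also gave as many for brain of the Hmgn3 line (2, highest other 763, 5 splits) and thymus of the Hmgn5 line (17, highest other 759, 5 splits). The highest called many times the real count, which points to a structure of these samples. So it was for tissue differences in the Hmgn3 line (38, highest other 59, 2 splits) and the Hmgn5 line (47, highest other 219, 3 splits, again a structure of the samples). Of 100 labellings for the differences between lines, the real one included, only the real one gave as many probes for liver (27, highest other 5), which makes chance less likely there. For thymus 2 did (9, highest other 173), and the higher count of the other labelling points to a structure of the samples. As many came up in 9 for brain (1, highest other 3) and 5 for spleen (3, highest other 14), so chance could not be excluded.

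The shared spleen change followed the replicate number of the labels inside groups of 1 genotype: the mean Spearman correlation over the 6 groups was 0.80 (6 of 6 positive, permutation p = 0.0002, adjusted p = 0.0008 over 4 tissues), against -0.17, 0.22 and 0.33 in brain, liver and thymus. Removing the median change of each of 20 intensity bins left the lowest correlation between lines at 0.514, against 0.513 before. The resemblance was thus not carried by a trend of the median change with intensity. Arrays of a set shared their quantiles, which leaves little such trend to remove, so this does not decide whether the authors' normalization played a part. Other effects of the normalization were not tested. A pooled spread smaller than a line's own was not seen at the median. The ratio of own to pooled variance in spleen was 0.962, 0.951 and 0.927 in the Hmgn1, Hmgn3 and Hmgn5 lines. The spread also enters only the calls, not the log2 changes that correlated between lines. With the number as a covariate the counts went to 0, 2 and 0, and the median change of the 572 Hmgn1-line probes fell to 0.25 (SE 0.166) from 0.53 (SE 0.129), a smaller change and not only a wider error. A candidate explanation is an order of dissection or array handling along the numbers, with wild types before mutants, which the sources used here do not state. A change shared by HMGN loss in 3 lines was not tested apart from it and stays open, though genotype alone gives no trend inside wild types. The covariate assumes that mutants follow wild types by 4 steps and partly overlaps with genotype.

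In the labelled Hmgn1 mutants a larger share of probes passed near Hmgn1 than on other chromosomes. Fisher exact p was 0.000102 over the 4 tissues as planned, and 4.22e-13 with spleen left out after its changes were seen. That test takes probes as independent, though neighbouring genes and both Cbr3 probes were among them. Chance placement is therefore less likely and not excluded. Weaker binding of probes to variants in linked DNA was tested first over all 8 changes, of which 4 were rises, and this did not decide it. Because that test was undecided, 2 more were added over the same 6 genes: Cbr3, Olig1 and Cryzl1 had opposite signs in different tissues (highest adjusted p of the difference 0.0444), which decides nothing, since they were picked for those signs and Mrap (0.0024), Ttc3 (0.0377) and Pigp (0.0434) passed the same test. Of 4 genes with further probes, 3 had another probe that moved with the first, while 0 of 7 further Ttc3 probes did, so for the falls of Ttc3, and of Mrap, which has 1 probe, it cannot be told apart from lower expression. Foreign DNA near the mutation and loss of HMGN1 were not measured, and both stay open.

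In thymus of the Hmgn3 line 2 of 4 labelled mutants lay above the highest wild type for skeletal muscle genes, which may, as a hypothesis, come from striated muscle attached to single thymi. Scores of 8.08 and 7.82 in 1 labelled Hmgn1 mutant and 1 Hmgn5-line wild type show that the signal was not tied to the Hmgn3 genotype. The 9 other lists called in this thymus lost their call with the muscle score as a covariate, though the median of immediate early genes went from 0.07 to 0.11. Without labelled mutant 1, at a muscle score of 8.26, smooth muscle genes alone lost their call (camera adjusted p = 0.0545). The labelled mutant at 7.76 stayed in that fit. The oxidative phosphorylation list, which muscle also expresses, went from an adjusted p of 2.02e-07 to 0.1001 by camera with the muscle score as a covariate, its median from 0.21 to 0.09. An effect of Hmgn3 on these genes was not tested apart from the muscle score.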

How the results depend on the processing

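Quantile normalization of the 3 lines together and the replicate number as a covariate were chosen after the data were seen, and the other alternatives below were planned. The cause of the shifts was not tested.

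With a floor of 1 before log2, brain of the Hmgn3 line gave 18 probes, liver of the Hmgn1, Hmgn3 and Hmgn5 lines 3, 21 and 29, spleen 25, 41 and 48, and thymus of the Hmgn5 line 11; differences between lines gave 10 in brain, 13 in liver and 9 in spleen. With no filter on dim probes, brain of the Hmgn1 and Hmgn3 lines gave 5 and 16, liver of the Hmgn1 line 17, spleen 373, 150 and 94, thymus of the Hmgn5 line 41 and line differences in brain 3. With the strict filter, brain of the Hmgn3 and Hmgn5 lines gave 4 and 2 and thymus of the Hmgn5 line 9. Array weights gave 7 in brain of the Hmgn1 line, 1006 and 327 in spleen of the Hmgn1 and Hmgn5 lines, and 48 and 11 in thymus of the Hmgn1 and Hmgn3 lines. With the lines of the tissue quantile-normalized together, brain of the Hmgn3 line gave 27, liver 3, 29 and 29, spleen of the Hmgn1 and Hmgn5 lines 111 and 338, thymus of the Hmgn5 line 7 and line differences in liver 10. With the arrays of the line and tissue only, brain of the Hmgn3 and Hmgn5 lines gave 0 and 2, liver of the Hmgn1 and Hmgn5 lines 1 and 15, spleen 3, 5 and 56, and thymus of the Hmgn1 and Hmgn5 lines 3 and 0. With values normalized within each tissue, average changes in the Hmgn5 line gave 62.

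With the order 1 to 8 as a covariate, brain of the Hmgn3 and Hmgn5 lines gave 1 and 1, liver of the Hmgn1 and Hmgn5 lines 1 and 1, spleen 0, 2 and 0, and thymus of the Hmgn1 and Hmgn5 lines 1 and 1. A slope along the order passed for 483 probes in spleen and 0 in the other tissues. The median change of the probes that had passed went from 0.53, 0.56 and 0.59 to 0.25, 0.29 and 0.30 in spleen. It stayed or grew in brain of the Hmgn3 line (0.56 to 0.67), liver of the Hmgn1 and Hmgn5 lines (0.67 to 0.69 and 0.76 to 0.75) and thymus of the Hmgn3 and Hmgn5 lines (1.46 to 1.47 and 0.72 to 0.79), where the larger error ended calls in all but the Hmgn3 thymus. It was smaller in brain of the Hmgn5 line (0.75 to 0.53) and thymus of the Hmgn1 line (1.10 to 0.88). Signs turned in spleen of the Hmgn1 line for Lyz2 (0.0288), the Snx2 probe at -0.78 (0.0217 with the covariate), Cxcl13 (0.0583) and the Hmgn1 probe (0.236). In spleen they also turned for Lyz2 (0.0410) and Cxcl13 (0.130) of the Hmgn3 line, and for smooth muscle genes of the 3 lines (-0.0612, -0.0397 and -0.0515). In thymus they turned for interferon-stimulated genes of the 3 lines (0.0356, 0.143 and 0.0768), T cell genes of the Hmgn1 (-0.00347, by the direction of camera) and Hmgn3 line (0.0423), antigen presentation genes of the Hmgn1 line (0.0391) and smooth muscle genes of the Hmgn3 line (-0.167).

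With the replicate number as a block, brain of the Hmgn3 and Hmgn5 lines gave 0 and 0, liver of the Hmgn1 and Hmgn5 lines 0 and 0, spleen of the Hmgn3 and Hmgn5 lines 2 and 0, and thymus 1, 0 and 0, while spleen of the Hmgn1 line gave 479. No comparison had every same-number correlation over 0.1. A single pair can decide that rule, so it does not settle whether the numbers pair the mice. In spleen the mean same-number correlation was 0.136, 0.0815 and -0.156 in the Hmgn1, Hmgn3 and Hmgn5 lines. Without the block, the same arrays of the Hmgn1 spleen had given 3 probes.

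Leaving out 1 array gave 0 to 1, 1 to 66 (without mutant 1) and 1 to 72 (without mutant 1) in brain of the Hmgn1, Hmgn3 and Hmgn5 lines, 4 to 15 (without mutant 1), 0 to 1 and 34 (without wild type 1) to 75 in liver, 9 (without wild type 1) to 1551 (without mutant 1), 8 (without wild type 1) to 717 (without mutant 1) and 8 (without mutant 4) to 416 (without wild type 4) in spleen, and 7 to 17 (without wild type 4), 2 to 3 and 9 (without mutant 2) to 26 (without wild type 1) in thymus. Leaving out 1 mouse gave 10 to 640, 0 to 85 and 17 to 95 for tissue differences and 29 to 976, 2 to 133 and 6 to 98 for average changes. Skeletal muscle genes in brain of the Hmgn3 line ranged from -0.0184 (without mutant 2) to 0.679, and acute phase genes in liver of the Hmgn3 line from -0.173 to 0.00513 (without wild type 2).

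Of 58 lists, 57 lost their call with an estimated correlation and 53 with fry. Of 91 named probes that passed, 76 lost their call with the order as a covariate, beside 5 of turned sign, 71 with the replicate block, 68 with the arrays of the line and tissue only and 56 with a floor of 1. Not run, since the raw signals could not be assigned to samples or the lines were normalized apart: raw signals with quantile normalization or with neqc, the chip as a block, the wild types of a tissue as 1 control group, and the test between wild types of the lines.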

Other observations

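Spleens of all lines varied in pancreatic acinar genes. The score of this list ran from 4.22 to 11.7 over the arrays, with labelled Hmgn1 mutants at 4.35, 4.37, 11.7 and 10.2 and Hmgn1-line wild types at 8.98, 4.60, 9.98 and 4.60. In thymus, Ltf, a neutrophil granule gene, averaged 39.6 in wild types and 1066 in labelled mutants of the Hmgn1 line and did not pass (log2 change 2.93, adjusted p = 0.45).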
